A study of Zea mays with 45 samples.

How the data were processed

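RNA from maize leaves was measured on the Affymetrix maize array. Per the labels, plants grew in days of 14 h of light and 10 h of dark, and tissue was taken at the end of the day, at the end of the night and after 6, 14 and 24 h of extended night. The division zone was the tissue from 0 to 1.5 cm above the ligule and the elongation zone that from 3 to 4.5 cm; the mature zone lay further up. Each replicate was a pool of 5 plants per the labels, which give 3 replicates for each of 15 groups, or 45 arrays. The columns of 3 of these hold no values (replicate 3 of the elongation and mature zones at the end of the day, and replicate 2 of the mature zone at 6 h), so 42 arrays were used and these groups had 2. No value was missing in the used columns, and 0 columns belonged to other series.

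The deposited values are log2 signal intensities, which the authors made with RMA per the submitters' processing notes (background correction, quantile normalization and summary of the probes of each probe set). The RMA version and settings are not given in the sources used here. The values ran from 2.56 to 14.41 and were used as deposited. The table holds 17734 probe sets; 113 control probe sets and 66 probe sets for reporter and selection genes were left out, and 17555 were tested. The 66 were read apart, as a measure of how often probe sets with no maize target passed the test: their median level was 4.12, and 3 of them lay above the dim level used below. Median signals were 7.63, 7.61 and 7.41 in the division, elongation and mature zones.

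The annotation names 1 gene for 1452 probe sets (8.27%), several genes for 1, and none for 16102. These are 1108 different genes, of which 1060 matched a gene identifier of the reference gene table (assembly Zm-B73-REFERENCE-NAM-5.0, used for names only). Counts of called probe sets use all 17555, and named genes and lists only those with 1 gene. For 222 genes with more than 1 probe set the brightest was used in lists; where probe sets of a named gene were called in opposite directions the text says so. This also held for wall genes *expA4* in the mature zone over the night and *expB8* between the elongation and mature zones, and for *pdk1* in the elongation zone at 24 h.

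Group means of the 15 groups were fitted with lmFit and moderated with eBayes in limma 3.58.1 under R 4.3.3, with 27 residual degrees of freedom and 4 prior ones. The 22 comparisons were each zone's end of night against end of day, each zone's 6, 14 and 24 h against the end of the night, 14 h against the end of the day, the next zone along the leaf at the end of the day, and 5 interactions, in which the change of a growth zone was taken from that of the mature zone. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called under 0.05. The median SE was 0.117 for 3 against 3 arrays, 0.13 for 3 against 2 and 0.143 for 2 against 2; signal depth does not apply, and the number of arrays limits the precision. The fit was tested on simulated data with 200 changed probe sets. For the mature zone at 24 h, 47.8% of changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2 were found. There were 11 false calls among 173. The simulated noise was independent, with the same spread in all groups, which the fit assumes. It therefore cannot show how often real mature-zone probe sets are falsely called. In the real comparison 9 of the 66 reporter probe sets were called.

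Of 28 gene lists written by symbol before the data were examined, 24 had a member on the array and 13 had at least 5 genes and were tested with camera (preset correlation 0.01) against the other named genes, adjusted over the lists of a comparison. Those tested were photosystems and light harvesting (8 genes), Calvin and C4 cycles (8), starch synthesis (14), sucrose metabolism and transport (9), cytosolic ribosomal proteins (14), cell cycle and DNA replication (12), histones (5), expansins and primary wall (22), nitrate and ammonium assimilation (8), heat shock (6), proteasome and cysteine proteases (8), tubulins and actins (10) and glycolysis (7). Smaller lists were only counted: chlorophyll synthesis, starch degradation, amino acid breakdown and asparagine synthesis, fatty acid oxidation and glyoxylate cycle, lignin, dehydrins, mitochondrial respiration, SnRK1, mesophyll markers, bundle sheath markers and meristem KNOX genes. Before any test, 17 symbol matches of other genes were taken out. The wall list took cellulose synthase genes by symbol, *cesa10*, *cesa11* and *CesA12* among them. Its name thus does not make each member a primary wall gene. The list of tubulins and actins held only tubulin genes, and that of the proteasome and cysteine proteases held no proteasome gene. The latter held *mir3* and a second entry of that name (LOC100037824), and values given for *mir3* are those of the former. The count of each list was also made with p-values adjusted over the list alone, and the 2 counts were equal wherever no second one is given.

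The comparisons, thresholds, lists, named-gene rule and most alternatives were set before the data were examined. The rule names, for each comparison, the 3 rising and 3 falling genes with the largest differences among called genes whose replicate values do not overlap between groups (overlap was ignored for interactions), and of each list with 2 or more called members the 3 with the smallest adjusted p. A gene named in 1 zone may be given in the others. Alternatives were the replicate number as a fixed or random block, a fit of the compared groups alone, leaving out probe sets below the 30th percentile of mean signal (6.21; 12288 left), quantile normalization again, centring each array on its median, eBayes with trend and robust settings, array weights, a minimum of 1, and leaving out each array in turn. Lists were also tested with an estimated correlation, with fry (against no change, where camera compares a list with the other named genes), with the mean of a gene's probe sets and without dim probe sets. Added later were lists with every symbol match, tests against all probe sets, lists and named genes without replicate 3 of the mature zone at the end of the night, and 2 further groups of genes, chosen after the data were seen and given as counts and values only.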

Results

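Maize leaves were followed from the end of the day through a normal night and into a night extended by 6, 14 or 24 h, a treatment that starves the plant of carbon. Expression was read on an Affymetrix maize array in 3 zones along the growing leaf: the division zone at the base, the elongation zone above it and the mature zone. The 5 times and 3 zones make 15 groups. Each group held 3 arrays with values, except the elongation and mature zones at the end of the day and the mature zone at 6 h, which held 2. Each replicate was a pool of 5 plants, so SD, SE and p-values measure the spread between pools, and the number of arrays limits the precision. The SE and p-values use 1 spread per probe set shared over all 15 groups. Array weights, lower for noisier arrays, ran from 0.0983 to 0.823 in the mature zone and from 0.489 to 5.49 in the division zone. The shared SE can thus understate the spread in the mature zone and overstate it in the division zone. Differences below are on the log2 scale ± SE, and adjusted p-values come from limma over 17555 probe sets. Only 1108 genes could be named, so most of the called probe sets carry no name here. The 24 h samples share the clock hour of the end of the night and the 14 h samples that of the end of the day. The comparisons of 6 h and 14 h with the end of the night mix the hour of the day with the length of darkness.

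The leaf zone set most of the differences between arrays. The first principal component held 70.2% of the variance, of which 97.5% lay between zones. The second held 9.6%, with 81.0% of it between times. Every array lay nearest to its own group, with correlations within groups from 0.963 to 0.998. Replicate 3 of the mature zone at the end of the night stood apart on the first component, at −92.8 against −140.8 and −143.1 for the other 2, toward the growth zones. Because the end of the night is the reference of most comparisons, list counts of the mature zone that this array changes are given with and without it.

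**Figure D1:**
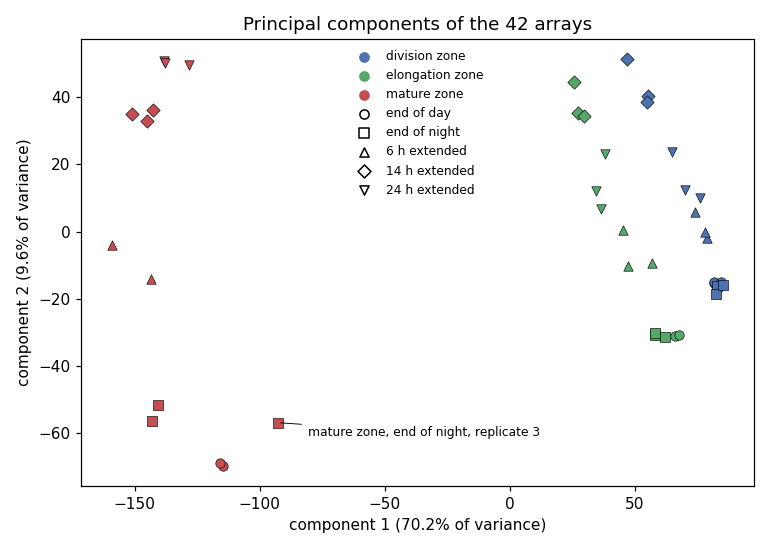
First principal component (70.2% of the variance) against the second (9.6%) for the 42 arrays, with colours for the leaf zones and markers for the times. Each point is 1 array; the zones separate along the first component, and replicate 3 of the mature zone at the end of the night lies at −92.8.

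At the end of the day, photosynthesis genes were higher with each step from the base of the leaf. All 8 genes of the photosystems and light harvesting were higher in the elongation zone (n = 2) than in the division zone (n = 3), among them *psah1*, a photosystem I subunit, by 2.77 ± 0.13, and *lhcb6*, a light-harvesting protein, by 2.22 ± 0.20. All 8 were higher again in the mature zone (n = 2), where *psan1* of photosystem I gained a further 5.14 ± 0.16 and *psad1* 4.65 ± 0.13. The steepest genes of the mature zone belong to C4 photosynthesis: the ferredoxin gene *fdx2* was higher than in the elongation zone by 9.21 ± 0.18 and *pep1*, PEP carboxylase, by 8.05 ± 0.30. The Rubisco activase gene *rca1* was higher by 7.80 ± 0.14 and the malic enzyme gene *me3* by 7.11 ± 0.12. All 8 genes of the Calvin and C4 cycles were higher there, as were all 4 mesophyll markers and all 4 bundle sheath markers, although the probe sets of 1 marker, *pdk1*, were called in opposite directions. Between the division and elongation zones, 4 genes of the Calvin and C4 list were higher and 2 lower. Both chlorophyll synthesis genes were higher at each step.

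Growth genes ran the other way at the step into the mature zone. From the elongation to the mature zone, 9 of 12 cell cycle and DNA replication genes were lower and none higher; the cyclin gene *cyc3* fell by 4.71 ± 0.40 and *cdc2*, the cell cycle kinase, fell by 2.48 ± 0.15. All 5 histone genes and 9 of 10 tubulin genes were lower, with *TUBB2* down at −2.60 ± 0.20 and 1 tubulin gene higher. The probe sets of *his1* were called in opposite directions. Of 14 cytosolic ribosomal protein genes 12 were lower, *RPL19* at −2.13 ± 0.24 and *rpl30* at −2.14 ± 0.24 among them, and 2 were higher. Of 8 protease genes 6 were higher, or 7 when adjusted over the list alone, with the vacuolar processing enzyme *see2b* at 3.87 ± 0.14 and the cysteine protease *mir3* at 2.79 ± 0.17. In the elongation zone, *yab14*, of the YABBY family that shapes leaves, fell by 5.31 ± 0.27 against the division zone. There *glu2*, a β-glucosidase, was higher by 6.04 ± 0.32, the expansin *expB4* by 2.41 ± 0.19 and the tubulin *tub4* by 2.80 ± 0.27, while *tub4* fell by 3.06 ± 0.29 at the next step.

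Single genes of sucrose and nitrogen supply were also higher in the mature zone, although their lists were not called. The sucrose-phosphate synthase gene *sps1* was higher in the mature than in the elongation zone by 7.39 ± 0.13 and the sucrose transporter *sut1* by 4.24 ± 0.18, in a list of 9 with 5 higher and 3 lower. The glutamine synthetase *GLN6* was higher by 5.39 ± 0.15 and the nitrate reductase *NNR1* by 3.33 ± 0.26, and 6 of 8 nitrate and ammonium genes were higher (list test adjusted p = 0.063). All 4 starch degradation genes were higher, while starch synthesis split into 4 higher and 3 lower of 14 and the primary wall list into 10 and 9 of 22. Called by the camera test (limma) at this step were photosystems (adjusted p = 1.3e-05) and Calvin and C4 cycles (adjusted p = 2.9e-06). By the same test cell cycle (adjusted p = 0.0094), histones (adjusted p = 0.017) and tubulins (adjusted p = 0.0094) were called. So were ribosomal proteins (adjusted p = 0.034) and proteases (adjusted p = 0.0094). With an estimated correlation the adjusted p became 0.086, 0.073, 0.33, 0.34, 0.38, 0.50 and 0.21 in that order, and the ribosomal list also lost its call without dim probe sets (adjusted p = 0.096). From the division to the elongation zone only the photosystems were called (adjusted p = 3.7e-06; adjusted p = 0.10 with an estimated correlation).

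Between the division and elongation zones 6831 probe sets differed (38.9%; 3149 higher, 3682 lower), and between the elongation and mature zones 12650 did (72.1%; 6340 higher, 6310 lower). Of the latter, 2682 were higher and 3380 lower by at least 1. Centring each array on its median moved the median of all probe sets for this step from 0.07 to 0.22. Of the 66 probe sets for reporter and selection genes, which are not maize genes, 22 were higher and 1 lower in the mature zone, none by as much as 1, so the smallest mature-zone differences deserve less weight.

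Over the normal night *thi1* and *thi2*, which act in thiamine synthesis, fell along the whole leaf. The transcript of *thi1* fell, at −3.42 ± 0.26 in the division zone (n = 3 and 3), −4.11 ± 0.29 in the elongation zone (n = 2 and 3) and −3.89 ± 0.29 in the mature zone (n = 2 and 3); *thi2* fell, at −2.28 ± 0.23, −2.95 ± 0.26 and −4.37 ± 0.26. A gene of ADP-glucose pyrophosphorylase, the entry step of starch synthesis, *AGP2* (LOC542737), fell, at −0.50 ± 0.10, −1.03 ± 0.11 and −1.67 ± 0.11. The other gene of that name, *Agp2* (LOC542072), gave −0.34 ± 0.45, −0.05 ± 0.51 and 0.92 ± 0.51. Photosystem genes rose before dawn in the growth zones: *psah1* by 1.35 ± 0.11 in the division and 1.05 ± 0.13 in the elongation zone, *psbQ1* of photosystem II by 0.92 ± 0.13 and 1.08 ± 0.14, while *lhcb5* fell by 1.29 ± 0.09 in the division zone. Of the 8 photosystem genes, 5 rose and 1 fell in the division zone (adjusted p = 0.00078; adjusted p = 0.22 with an estimated correlation) and 6 rose in the elongation zone (adjusted p = 2.8e-08; 0.031 with an estimated correlation), or 6 rose and 1 fell when adjusted over the list alone. None of the 8 changed in the mature zone. In the elongation zone 3 of 6 heat shock genes fell (adjusted p = 0.005; 0.038 with an estimated correlation), *hsp18* at −0.84 ± 0.12 among them, or 1 rose and 4 fell when adjusted over the list alone.

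In the mature zone protease genes fell as a list over the night, and single genes of water channels and walls changed. The aquaporin *pip1e* rose by 3.70 ± 0.16, the wall-loosening gene *xet1* by 2.86 ± 0.21 and *NNR1* by 1.81 ± 0.24. Also higher were the nitrite reductase *NIR*, by 1.15 ± 0.15, the kinase *SnrK1*, of the SNF1-related family that senses energy, by 1.24 ± 0.17, and the phosphofructokinase *pfk1*, by 1.33 ± 0.10. The cellulose synthases *cesa10* and *cesa7* fell, at −1.30 ± 0.19 and −1.15 ± 0.17, while the wall list of 22, with 3 higher and 10 lower, was not called (adjusted p = 0.11; 2 and 10 without replicate 3 of the end of the night, adjusted p = 0.17). Of 8 protease genes 7 fell, including *see1* at −1.81 ± 0.10 and *mir3* at −1.78 ± 0.15 (adjusted p = 0.00018; adjusted p = 0.094 with an estimated correlation); 6 of 8 fell without that replicate (adjusted p = 0.0018). The protease list was also called in the elongation zone, where 2 of 8 fell (3 when adjusted over the list alone; adjusted p = 0.017; adjusted p = 0.21 with an estimated correlation), *ccp1* at −0.63 ± 0.08. Of 14 ribosomal genes 2 rose and 7 fell in the mature zone (2 and 9 when adjusted over the list alone; adjusted p = 0.27), against 2 and 11 without that replicate (adjusted p = 0.0058).

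The night changed 1142 probe sets in the division zone (6.5%; 347 higher, 795 lower), 1106 in the elongation zone (6.3%; 477 and 629) and 7113 in the mature zone (40.5%; 3548 and 3565, where 3 reporter probe sets were called). The share higher was 30.4% and 43.1% in the growth zones, and 47.0% and 57.7% after centring the arrays, so no general direction is given there. The division-zone count was 732, 663 and 582 without end-of-day replicates 1 and 2 and end-of-night replicate 2. The elongation-zone count was 333, 604 and 686 without end-of-day replicates 1 and 2 and end-of-night replicate 3. Array weights gave 4792 and 2563, and a fit of the compared groups alone gave 2825 in the division zone and 2520 in the mature zone. In that last fit the mature zone no longer had more calls than the division zone. The contrast in counts thus depends on the spread shared by all groups. That fit was not like for like, since the end of the day had 2 arrays in the mature zone and 3 in the division zone. By at least 1 in the main fit, 22 rose and 56 fell in the division zone, against 665 and 821 in the mature zone.

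After 6 h of extended night *lkrsdh1*, *GBF1* and *SnrK1* had risen in all 3 zones. The transcript of *lkrsdh1*, which degrades lysine, rose by 2.97 ± 0.27 in the division zone, 3.38 ± 0.27 in the elongation zone (n = 3 and 3 in both) and 1.53 ± 0.30 in the mature zone (n = 3 and 2). Asparagine synthetase, *asn1*, which stores nitrogen when carbon is short, rose by 3.90 ± 0.48 in the elongation zone and 2.50 ± 0.53 in the mature zone (1.88 ± 0.52 without replicate 3 of the end of the night) and was not called in the division zone (1.44 ± 0.48, adjusted p = 0.096). The G-box factor *GBF1* rose by 2.65 ± 0.18, 2.50 ± 0.18 and 2.53 ± 0.20 from base to tip, and *SnrK1* by 0.96 ± 0.16, 1.83 ± 0.16 and 2.64 ± 0.17. The nitrate reductase *NNR1* fell, at −1.83 ± 0.21 in the elongation zone and −1.79 ± 0.24 in the mature zone. In the mature zone 1 of the 2 alternative oxidase genes named *aox1* (LOC542074) rose by 2.76 ± 0.31 and the other (LOC542073) fell by 0.57 ± 0.13. There the starch synthase *GBSSIIa* rose by 2.51 ± 0.20 and the scarecrow-like gene *Scl1* by 3.02 ± 0.33, while the invertase *ivr2* fell by 2.14 ± 0.33, *cesa7* at −1.91 ± 0.17 and *GLN6* at −1.57 ± 0.14.

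The ribosomal protein genes fell as a group in the mature zone at 6 h, with a median of −0.84. Of 14, 13 were lower, or 1 higher and 13 lower when adjusted over the list alone. The camera adjusted p was 0.00099, and 0.66 with an estimated correlation. Without replicate 3 of the end of the night 13 were lower, with a median of −0.57 (camera adjusted p = 0.0042). The most certain were *rps27* at −0.92 ± 0.14, *RPL10* at −0.85 ± 0.12 and *rps13* at −0.83 ± 0.11, and all 3 lost their calls in a fit of the compared groups alone. Of 10 tubulin genes 6 fell, or 7 when adjusted over the list alone (camera adjusted p = 0.16). Without replicate 3 of the end of the night 3 fell. In the division zone 3 of 8 photosystem genes rose, *lhcb5* by 1.29 ± 0.09 and *psah1* by 0.91 ± 0.11 among them (3 rose and 1 fell when adjusted over the list alone; adjusted p = 0.0054; adjusted p = 0.77 with an estimated correlation). In the elongation zone 3 rose and 1 fell, or 4 and 1 when adjusted over the list alone (camera adjusted p = 0.033, and 0.52 with an estimated correlation). Of the 22 genes of the wall list 2 fell there, or 4 when adjusted over the list alone, *cesa8* at −0.60 ± 0.14 among them. The camera adjusted p of the wall list was 0.033, and 0.52 with an estimated correlation. Both calls of the elongation zone were lost without dim probe sets (adjusted p = 0.081 and 0.083).

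At 6 h, 712 probe sets had changed in the division zone (4.1%; 552 higher, 160 lower), 1582 in the elongation zone (9.0%; 832 and 750) and 6869 in the mature zone (39.1%; 3419 and 3450). The share higher in the division zone was 77.5%, and 67.3% after centring. The division-zone count was 388 without replicate 3 of 6 h and 430 without replicate 2 of the end of the night, and the elongation-zone count was 716 without replicate 3 of 6 h. Array weights gave 5257 and 3337 in these zones. A fit of the compared groups alone gave 1859 in the division zone and 2180 in the mature zone, so the contrast in counts depends on the shared spread. By at least 1 in the main fit, 144 rose and 10 fell in the division zone, against 524 and 844 in the mature zone. Of the 66 reporter probe sets, 8 were called higher in the mature zone.

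By 14 h *asn1*, *gdh1*, *lkrsdh1* and *mas1* had risen along the whole leaf. Against the end of the day, which shares the clock hour, *asn1* rose by 6.20 ± 0.48 in the division zone (n = 3 and 3), 6.75 ± 0.53 in the elongation zone and 5.48 ± 0.53 in the mature zone (n = 2 and 3 in both). Glutamate dehydrogenase, *gdh1*, which releases carbon skeletons from glutamate, rose by 3.81 ± 0.24, 3.13 ± 0.26 and 2.74 ± 0.26, and *lkrsdh1* by 5.15 ± 0.27, 5.27 ± 0.30 and 2.52 ± 0.30. Malate synthase of the glyoxylate cycle, *mas1*, rose by 4.42 ± 0.37, 5.17 ± 0.41 and 4.53 ± 0.41, while *ICL*, the other gene of its list, was not called (−0.06 ± 0.10, 0.05 ± 0.11 and 0.12 ± 0.11). The proteinase inhibitor *wip1* rose by 5.18 ± 0.68, 5.98 ± 0.76 and 4.6 ± 0.76, and *SnrK1* by 2.0 ± 0.16, 3.37 ± 0.17 and 2.78 ± 0.17. The heat shock gene *hsp22* fell, at −3.40 ± 0.27, −4.01 ± 0.30 and −2.70 ± 0.30. In the growth zones *pcna1*, the replication clamp, fell, at −1.69 ± 0.33 in the division and −2.62 ± 0.37 in the elongation zone. Of 12 cell cycle genes 3 rose and 7 fell in each of these zones (3 and 8 in the division zone when adjusted over the list alone), and the list was not called.

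In the mature zone at 14 h the cellulose synthases *cesa7* and *cesa10* fell, at −4.37 ± 0.17 and −3.08 ± 0.19 against the end of the day, *GLN6* at −2.78 ± 0.14, the tubulin *tub3* at −2.76 ± 0.17 and the glycolytic enolase *eno1* at −1.74 ± 0.09. Ribosomal genes were the only list called: 1 rose and 12 fell (1 and 13 when adjusted over the list alone; adjusted p = 0.0059; adjusted p = 0.72 with an estimated correlation), *rpl29* at −1.53 ± 0.10 and *rpl39* at −1.63 ± 0.14. Against the end of the night 13 fell (adjusted p = 0.014; adjusted p = 0.63 with an estimated correlation), and 12 did without its replicate 3 (adjusted p = 0.045). Without dim probe sets this call was lost (adjusted p = 0.061). The probe sets of *rpp3* were called in opposite directions in both comparisons, and those of *RPL10* against the end of the night. In both comparisons 8 of 10 tubulin genes fell. The camera adjusted p was 0.079 against the end of the day and 0.074 against the end of the night. In the latter 7 fell without that replicate (camera adjusted p = 0.15). No list was called in the growth zones at 14 h. In the division zone 5 protease genes rose and 1 fell against the end of the night (adjusted p = 0.29), with 5 and 2 in the elongation zone (adjusted p = 0.18) and 7 and 1 in the mature zone (adjusted p = 0.074; 5 and 1 without that replicate, adjusted p = 0.15).

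Against the end of the night, *asn1* at 14 h was higher by 6.12 ± 0.48, 6.50 ± 0.48 and 3.75 ± 0.48 from base to tip, the last being 3.13 without replicate 3. The cinnamoyl-CoA reductase *cncr1* fell, at −2.70 ± 0.21, −3.13 ± 0.21 and −4.57 ± 0.21, and *ivr2* at −2.18 ± 0.29, −3.05 ± 0.29 and −5.13 ± 0.29. The carotenoid gene *psy2* fell by 3.74 ± 0.15 in the mature zone. Against the end of the day 7822 probe sets changed in the division zone (44.6%; 3614 higher, 4208 lower), 7984 in the elongation zone (45.5%; 3809 and 4175) and 10678 in the mature zone (60.8%; 5970 and 4708). Against the end of the night the counts were 7640 (43.5%; 3637 and 4003), 8129 (46.3%; 3952 and 4177) and 10071 (57.4%; 5625 and 4446), the last 5589 in a fit of the compared groups alone. Of the 66 reporter probe sets, 21 were called in the mature zone against the end of the day and 19 against the end of the night.

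**Figure D2:**
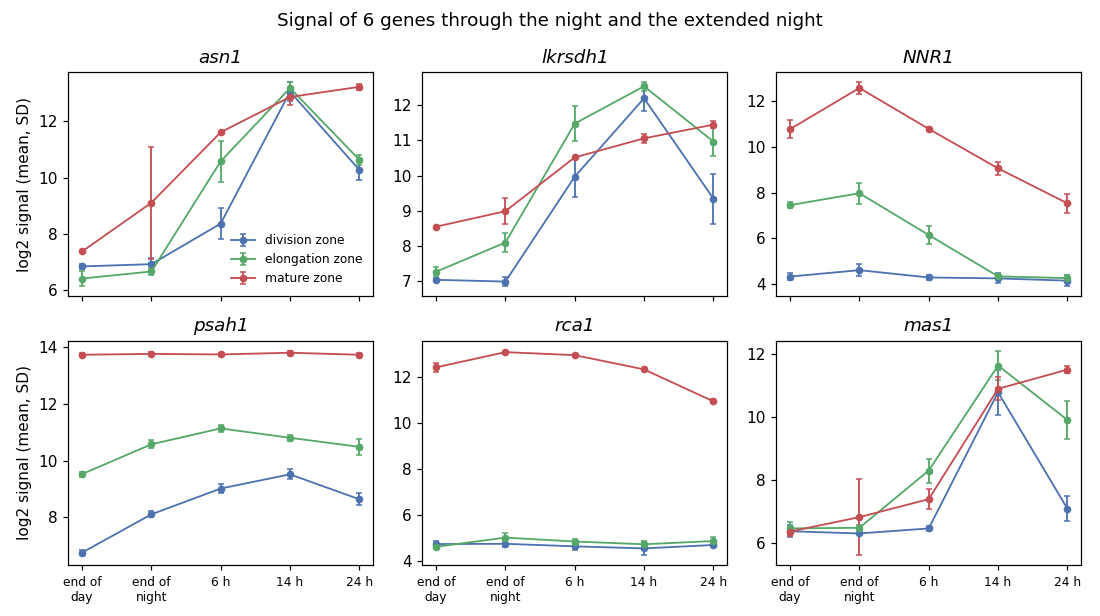
Mean log2 level (points) with SD between pools (bars) at the 5 times in the 3 leaf zones, 2 or 3 arrays per group, for 6 genes: *asn1*, *lkrsdh1*, *NNR1*, *psah1*, *rca1* and *mas1*. At 24 h *asn1* stood 3.34 to 4.11 above the end of the night in all zones, while *rca1* fell by 2.14 in the mature zone.

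At 24 h, at the clock hour of the end of the night, *asn1*, *gdh1* and *lkrsdh1* were still higher along the leaf. The transcript of *asn1* was higher by 3.34 ± 0.48 in the division zone, 3.95 ± 0.48 in the elongation zone and 4.11 ± 0.48 in the mature zone (n = 3 and 3 in each; 3.49 in the mature zone without replicate 3 of the end of the night). That of *gdh1* was higher by 2.14 ± 0.24, 1.36 ± 0.24 and 2.31 ± 0.24, and that of *lkrsdh1* by 2.36 ± 0.27, 2.87 ± 0.27 and 2.46 ± 0.27. Both genes of the amino acid list rose in every zone. In the division zone the vacuolar proton pump *vpp1* rose by 3.20 ± 0.20 and the lipid transfer gene *PLTP* by 3.17 ± 0.28, while *bx1*, the first gene of benzoxazinoid synthesis, fell by 3.14 ± 0.27. There 5 photosystem genes fell and 1 rose (adjusted p = 0.087), and both chlorophyll synthesis genes fell, *por*, protochlorophyllide reductase, at −1.12 ± 0.11. No list was called in the division zone.

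In the elongation zone photosystem genes fell and protease genes rose by 24 h. The light-harvesting gene *Cab-m7* fell by 2.99 ± 0.20 and *psbs1* at −1.12 ± 0.15; 5 of 8 photosystem genes fell and none rose (adjusted p = 0.0092; adjusted p = 0.56 with an estimated correlation). The cysteine protease *ccp1* rose by 0.90 ± 0.07, *see2a* by 1.06 ± 0.13 and *mir3* by 0.88 ± 0.14, and 5 of 8 protease genes rose (7 when adjusted over the list alone; adjusted p = 0.008; adjusted p = 0.40 with an estimated correlation). The glyoxylate gene *mas1* rose by 3.43 ± 0.37 and *NNR1* fell by 3.72 ± 0.21. The replication clamp *pcna1* fell by 1.95 ± 0.33, and of 12 cell cycle genes 4 rose and 5 fell. Of 5 histone genes 3 fell, or 4 when adjusted over the list alone, *hon101* at −0.80 ± 0.13.

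In the mature zone genes of carbon fixation and nitrate use fell by 24 h. All 8 genes of the Calvin and C4 cycles were lower (median −1.09; adjusted p = 0.029; adjusted p = 0.38 with an estimated correlation), with *rca1* down at −2.14 ± 0.12, the plastid GAPDH genes *gpa1* at −1.63 ± 0.13 and *gpb1* at −1.35 ± 0.07, and *mdh6* at −1.64 ± 0.16. All 4 mesophyll markers and all 4 bundle sheath markers were lower, by medians of −1.05 and −1.08. Of 8 nitrate and ammonium genes 5 fell (adjusted p = 0.047; adjusted p = 0.32 with an estimated correlation), *NNR1* at −5.05 ± 0.21, *NIR* at −3.51 ± 0.14 and *GLN6* at −2.87 ± 0.12; 6 fell without replicate 3 of the end of the night (adjusted p = 0.042). Of 8 protease genes 6 rose and 1 fell (adjusted p = 0.043; adjusted p = 0.38 with an estimated correlation; adjusted p = 0.052 without that replicate): *see2a* rose by 1.62 ± 0.13 and *mir3* by 1.59 ± 0.14, while *see2b* fell by 1.92 ± 0.11. All 3 calls were lost without dim probe sets (adjusted p = 0.053 for each). The nitrate call was also lost with the mean of a gene's probe sets (adjusted p = 0.058) and with every symbol match (adjusted p = 0.054), and the protease call against all probe sets (adjusted p = 0.050).

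The 3 largest rises among named genes of the mature zone were *mas1* at 4.69 ± 0.37, the cysteine proteinase inhibitor *cpi2* at 4.37 ± 0.20 and *Scl1* at 4.23 ± 0.29. The largest falls were *cncr1* at −5.61 ± 0.21, *ivr2* at −5.08 ± 0.29 and *NNR1*. Single wall, starch and sucrose genes of the mature zone also changed, without their lists being called. Of the 22 genes of the wall list 4 rose and 13 fell, *cesa7* at −3.82 ± 0.15 and *expB6* at −3.19 ± 0.19 among them. The camera adjusted p of the wall list was 0.064. Without replicate 3 of the end of the night 3 rose and 13 fell (camera adjusted p = 0.052). Of 10 tubulin genes 7 fell, or 8 when adjusted over the list alone, *tub3* at −2.04 ± 0.15 among them. The camera adjusted p of the list was 0.064, and 0.18 without that replicate. The probe sets of *tub6* were called in opposite directions. In starch metabolism *ss1*, a starch synthase, fell by 2.02 ± 0.12 and the isoamylase *iso2* at −2.42 ± 0.11, while the branching enzyme *sbe1* rose by 1.34 ± 0.10 and the pullulanase *zpu1* by 0.99 ± 0.14. The sucrose-phosphate synthase *sps1* fell by 1.99 ± 0.11 and the sucrose synthase *sh1* rose by 0.94 ± 0.12. The lignin gene *BM1* fell by 3.39 ± 0.19, *eno1* at −1.87 ± 0.08 and the mitochondrial ATP synthase gene *ATP2* at −0.66 ± 0.05, while *SnrK1* rose by 2.13 ± 0.16.

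The other lists at 24 h are given as genes higher and lower in the division, elongation and mature zones, and none was called. Starch synthesis (14 genes) had 1 and 4, 1 and 5, and 2 and 3, the last 3 and 3 without replicate 3 of the end of the night, with 1 and 6 in the elongation zone when adjusted over the list alone. Starch degradation (4 genes) had 1 and 1, 1 and 1, and 1 and 2, with 2 and 1 in the elongation zone when adjusted over the list alone. Sucrose metabolism (9) had 2 and 1, 3 and 2, and 3 and 3, the last 4 and 3 without that replicate. Fatty acid oxidation and glyoxylate (2) had 0 and 0, 1 and 1, and 1 and 0. Ribosomal proteins (14) had 1 and 1, 2 and 5, and 0 and 8, the last 2 and 5 without that replicate. Cell cycle (12) had 3 and 0 in the division zone and 3 and 4 in the mature zone, where it was 4 and 2 without that replicate. Histones (5) had 0 and 1 in the division zone (0 and 2 when adjusted over the list alone) and 3 and 1 in the mature zone, where the probe sets of *his1* were called in opposite directions. Lignin (3) had 0 and 1, 0 and 2, and 0 and 2.

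Heat shock genes (6) had 1 and 1, 0 and 1, and 2 and 1, the last 1 and 1 without replicate 3 of the end of the night, and dehydrins (3) 0 and 1, 0 and 1, and 1 and 1. Glycolysis (7) had 1 and 2, 1 and 3, and 0 and 5, the last 1 and 5 when adjusted over the list alone and 0 and 4 without that replicate. Mitochondrial respiration (4) had 0 and 0, 0 and 2, and 0 and 2. The SnRK1 list (2) had 0 and 0, 1 and 0, and 1 and 0, and meristem KNOX genes (4) 0 and 0, 1 and 0, and 2 and 1, the last 2 and 2 without that replicate. In the growth zones the mesophyll markers had 0 and 1, then 1 and 2, and the bundle sheath markers 1 and 0 in both. The Calvin and C4 list had 1 and 1, then 2 and 2, the nitrate list 1 and 2, then 1 and 3, the wall list 3 and 1, then 6 and 3, and the tubulins 2 and 0, then 1 and 0. Proteases had 3 and 0 in the division zone. In the mature zone photosystems had 0 and 2 and chlorophyll synthesis 0 and 1, or 0 and 2 without that replicate.

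At 24 h, 5762 probe sets had changed in the division zone (32.8%; 3137 higher, 2625 lower), 7442 in the elongation zone (42.4%; 3820 and 3622) and 10161 in the mature zone (57.9%; 5542 and 4619). Changes of at least 1 numbered 560, 1167 and 3460. The share higher in the division zone was 54.4%, and 36.0% after centring, so no general direction is given there; array weights gave 9009 probe sets. Of the 66 reporter probe sets 9 were called in the mature zone, and the 3′ minus 5′ signal of the cyclophilin control, a measure of RNA quality, rose by 0.41 ± 0.10 there and by 0.35 ± 0.11 and 0.40 ± 0.08 in the growth zones.

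**Figure D3:**
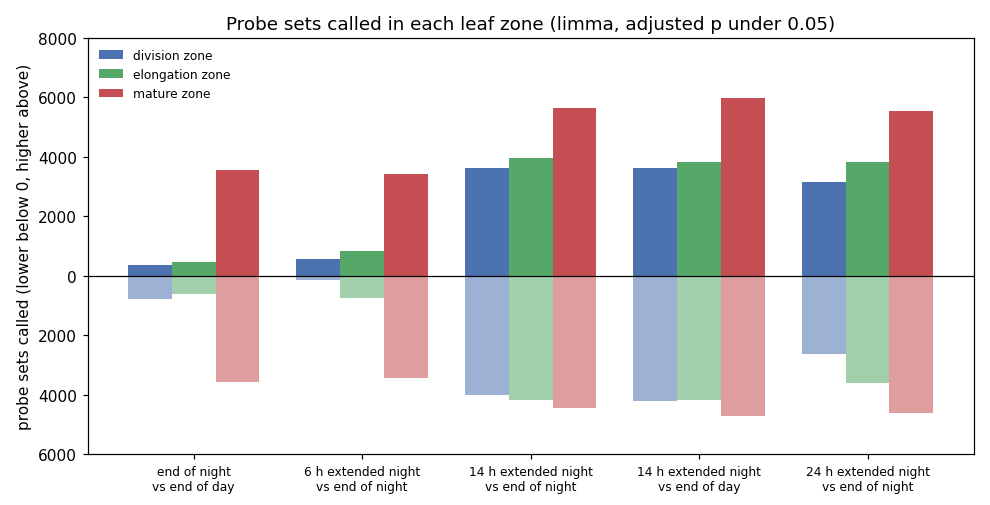
Number of probe sets called higher (above 0) and lower (below 0) in each leaf zone for the night and for 6, 14 and 24 h of extended night, at adjusted p under 0.05 of 17555 probe sets, with 2 or 3 arrays per group. The mature zone had 6869 at 6 h against 712 in the division zone, and 10161 against 5762 at 24 h. In a fit of the compared groups alone the contrast between these zones was small at 6 h and turned round for the night.

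The response to 24 h of extended night differed between the zones. Genes of the Calvin cycle fell further in the mature zone than at the base. The change of *rca1* was −0.05 ± 0.12 (adjusted p = 0.78) in the division zone against −2.14 ± 0.12 in the mature zone. The difference was −2.09 ± 0.17 by the interaction test (n = 3 in each group). At the end of the day all 8 genes of the Calvin and C4 list were higher in the mature than in the elongation zone. The step was 7.80 for *rca1*. A low level in a growth zone leaves little room for a fall, so these differences, also by list, may partly reflect the level of expression. Other genes turned in opposite directions, among them *PLTP*, with a rise of 3.17 ± 0.28 at the base and −2.54 ± 0.28 in the mature zone, and *vpp1*, with 3.20 ± 0.20 and −1.66 ± 0.20. The tubulin *tub3* rose by 0.58 ± 0.15 at the base and 0.64 ± 0.15 in the elongation zone, against −2.04 ± 0.15 in the mature zone. The cellulose synthase *cesa7* differed from the division zone by −3.88 ± 0.21 and *NNR1* by −4.59 ± 0.30. Compared with the elongation zone, the mature zone differed most among named genes in *cpi2*, at 4.28 ± 0.28, and in the aquaporin *tip2a*, at −5.60 ± 0.50. The interaction passed for 8687 probe sets against the division zone (49.5%; 4841 higher, 3846 lower) and 8546 against the elongation zone (48.7%; 4687 and 3859), with 10 and 6 of the 66 reporter probe sets. Centring moved the median of all probe sets in the former from 0.10 to 0.21.

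By list, the Calvin and C4 cycles fell further in the mature zone than in the division zone (8 of 8; adjusted p = 0.027; adjusted p = 0.45 with an estimated correlation) and than in the elongation zone (8 of 8; adjusted p = 0.026; adjusted p = 0.52 with an estimated correlation), with the probe sets of 1 member, *pdk1*, called in opposite directions in both. The primary wall list had 1 higher and 13 lower (12 lower without replicate 3 of the end of the night; adjusted p = 0.03; adjusted p = 0.45 with an estimated correlation), then 3 and 12 (3 and 13 when adjusted over the list alone; adjusted p = 0.049; adjusted p = 0.52 with an estimated correlation). The nitrate list had 1 higher and 6 lower in both (adjusted p = 0.03 and adjusted p = 0.049; adjusted p = 0.25 and 0.41 with an estimated correlation), *NIR* differing by −3.03 ± 0.19 and −2.83 ± 0.19. The tubulins had 9 and 8 of 10 lower (adjusted p = 0.03 and adjusted p = 0.049; adjusted p = 0.60 and 0.55 with an estimated correlation). Without replicate 3 of the end of the night the tubulin counts were 6 and 6 (adjusted p = 0.067 and adjusted p = 0.10), and the histone list was called against the elongation zone, with 4 higher (adjusted p = 0.042). Without dim probe sets the wall and tubulin calls against the division zone were lost (adjusted p = 0.051 and 0.079), and so were all 4 calls against the elongation zone (adjusted p = 0.071 for the Calvin and C4 cycles, 0.079 for walls and nitrate and 0.094 for tubulins). Against the elongation zone walls, nitrate and tubulins also lost their calls with every symbol match (adjusted p = 0.057 for each), and nitrate and tubulins with the mean of a gene's probe sets (adjusted p = 0.059 for both).

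The zones already differed at 6 h and over the normal night. At 6 h the mature zone differed from the division zone for *nip2b*, an aquaporin, by 3.02 ± 0.30, for *GBSSIIa* by 2.30 ± 0.27 and for *ivr2* by −2.23 ± 0.44. Ribosomal genes fell further in the mature zone than in the division zone (12 of 14; 13 when adjusted over the list alone; adjusted p = 0.0017; adjusted p = 0.57 with an estimated correlation) and than in the elongation zone (12 of 14; adjusted p = 0.002; adjusted p = 0.62 with an estimated correlation). These were 11 and 9 without replicate 3 of the end of the night (adjusted p = 0.0076 and adjusted p = 0.017). The interaction at 6 h passed for 4636 probe sets against the division zone (26.4%; 2132 higher, 2504 lower) and 4124 against the elongation zone (23.5%; 1947 and 2177), and for 2919 and 2625 without replicate 3 of the mature zone at 6 h. The share higher was 46.0% against the division zone, and 59.0% after centring; 7 and 3 reporter probe sets were called. A fit of the compared groups alone gave 2357 against the elongation zone.

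Over the normal night the mature zone differed from the division zone for *pip1e* by 3.67 ± 0.22 and for *xet1* by 2.77 ± 0.29. The cysteine protease *see1* fell, at −0.44 ± 0.09 at the base and −1.81 ± 0.10 in the mature zone, a difference of −1.36 ± 0.14, and 6 of 8 protease genes fell further in the mature zone (adjusted p = 0.0016; adjusted p = 0.21 with an estimated correlation). In all, 5078 probe sets passed (28.9%; 2546 higher, 2532 lower). Without replicate 3 of the end of the night 2 further lists were called, ribosomal proteins with 2 higher and 10 lower (adjusted p = 0.0044) and tubulins with 5 lower (adjusted p = 0.047).

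Part of the response was common to the leaf. At 24 h, 1625 probe sets were higher in all 3 zones, against 215.5 if the zones were independent, and 855 were lower, against 142.5. At 14 h, against the end of the night, 2034 were higher and 1600 lower, against 262.4 and 241.2. The growth zones were close to each other: at 24 h, 2595 were higher in both, 1880 lower in both and 28 opposite. The division and mature zones were opposite for 1192 probe sets at 24 h, and higher in both for 1795 and lower in both for 1044. The zones share no arrays, but same-numbered arrays of the division and elongation zones deviated together at the end of the night, 14 h and 24 h. These zones thus did not meet the independence that the expected numbers assume. The fit also gave each probe set the same spread in all zones. A probe set with a small spread is therefore more readily called in every zone, which raises the shared counts in advance. The excess over the expected numbers alone thus cannot show a common response. The shared spread does not set the direction of a change, so it does not favour same over opposite calls.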

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

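The results here were flagged because the change in the mature zone differed from that of a growth zone by the interaction test of limma (n = 2 or 3 arrays per group). The interactions were planned before the data were examined. The tests of 3′ minus 5′ signal, the count without replicate 3 of the end of the night and the ratio over all tested probe sets were chosen only after the results were seen. For the pattern of replicate 3 and that of the 24 h to 14 h ratio no biological explanation was tested. All differences are on the log2 scale, mature zone minus growth zone.

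At 6 h of extended night 4636 probe sets differed between the mature and division zones, with *nip2b* at 3.02, *gst2* at 2.99, *aox1* (LOC542074) at 2.81, *ivr2* at −2.23, *PEAMT* at −2.07 and *tha9* at −1.97. The ribosomal protein list was called (adjusted p = 0.0017; adjusted p = 0.57 with an estimated correlation). Between the mature and elongation zones 4124 differed, with *aox1* (LOC542074) at 3.15, *nip2b* at 3.07, *gst2* at 2.72, *thi1* at −2.24, *lkrsdh1* at −1.85 and *tha9* at −1.85, and the ribosomal list was called again (adjusted p = 0.002; adjusted p = 0.62 with an estimated correlation).

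At 24 h, 8687 probe sets differed between the mature and division zones, with *cpi2* at 4.16, *mas1* at 3.90, *Scl1* at 3.33, *PLTP* at −5.71, *ivr2* at −5.18 and *vpp1* at −4.87. The lists called were Calvin and C4 cycles (adjusted p = 0.027), primary wall (adjusted p = 0.03), nitrate (adjusted p = 0.03) and tubulins (adjusted p = 0.03). All 4 calls were lost with an estimated correlation (adjusted p = 0.45, 0.45, 0.25 and 0.60), and those of walls and tubulins also without dim probe sets (adjusted p = 0.051 and 0.079). That of tubulins was lost without replicate 3 of the end of the night too (adjusted p = 0.067). Between the mature and elongation zones 8546 differed, with *cpi2* at 4.28, *rpo2* at 3.49, *pdi* at 3.06, *tip2a* at −5.60, *cesa7* at −4.21 and *psy2* at −4.02, and the same lists were called (adjusted p = 0.026, 0.049, 0.049 and 0.049). These calls too were lost with an estimated correlation (adjusted p = 0.52, 0.52, 0.41 and 0.55) and without dim probe sets (adjusted p = 0.071, 0.079, 0.079 and 0.094), and that of tubulins without replicate 3 (adjusted p = 0.10).

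Over the normal night 5078 probe sets differed between the mature and division zones, with *pip1e* at 3.67, *AGA3b* at 3.39, *xet1* at 2.77, *rpo2* at −3.91, *gst19* at −3.25 and *tip4a* at −3.11, and the protease list was called (adjusted p = 0.0016; adjusted p = 0.21 with an estimated correlation).

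The first pattern weighed is replicate 3 of the mature zone at the end of the night, which lay toward the growth zones. Of 271 probe sets high in the growth zones, 94.5% were above both other arrays of the group, by a median of 2.21, against 17.3% of 75 and 8.1% of 74 for replicates 1 and 2, while 293 probe sets of the mature zone moved by −0.15. The shares of replicates 1 and 2 were held down in advance, since they had to exceed replicate 3 too. The shift of replicate 3 restates its place on the first component. It fits a pool holding less mature tissue, with an implied share of 14.9% (quartiles 7.9% and 34.2%). RNA carried over between samples would look the same. A large shift of the sampling hour toward either neighbouring time was excluded. By medians over 35 and 38 probe sets, the array moved −8.7% of the way toward the end of the day and −7.6% toward 6 h. Replicate 1 moved 12.7% toward 6 h, so the measure cannot exclude a small shift. RNA quality did not stand out: 0 of 3 control genes had a 3′ minus 5′ signal outside that of the other mature-zone arrays. These genes alone cannot exclude it.

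The second pattern is the larger change of the mature zone than of the division zone at 24 h. RNA quality was not settled as its cause, since 3 control genes read by a rule set after the results are too few. In the mature zone their 3′ minus 5′ signal changed by −0.50 ± 0.13 (actin), 0.01 ± 0.15 (GAPDH) and 0.41 ± 0.10 (cyclophilin). A general loss of 5′ signal would raise all 3, and actin fell. Cyclophilin changed by 0.35 ± 0.11 in the division zone too. Replicate 3 of the end of the night was excluded as the cause, with 8766 probe sets called without it. The calls of 10 of 66 reporter probe sets leave part of the smallest differences open. The biological explanation the design gives is a different response of the zones to darkness.

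The last pattern is the smaller change of the division zone at 24 h (560 probe sets changed by at least 1) than at 14 h (1463) against the end of the night. With 14 h set against the end of the day, so that each time has its own clock hour, the root mean square change over all tested probe sets at 24 h was 0.64 times that at 14 h in the division zone (0.58 to 0.69 with 1 array left out; 0.63 and 0.65 under the 2 scalings), 0.73 (0.69 to 0.76) in the elongation zone and 0.96 (0.95 to 0.98) in the mature zone, and the difference between zones was not tested. This measure, which chooses no probe sets, excludes a single array, scaling and the hour of the reference as the cause, and leaves open a response to darkness that itself varies with the hour. The planned median ratio cannot decide, since choosing probe sets by their change at 14 h lowers it in advance: it was 0.43 over 1535 probe sets of the division zone (0.38 to 0.47 with 1 array left out; 0.43 under both scalings), 0.61 over 2015 of the elongation zone and 0.63 over 3727 of the mature zone. Over the 560 of the division zone chosen at 24 h, which raises it, the ratio was 0.78 (0.73 to 0.87 with 1 array left out).

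Regrouping the same arrays gave the following counts. With 10 splits, which are too few for a share under 0.05, the real split had the highest count, 1 of 10, in each comparison tried. Real and highest other counts were 1142 and 1 for the night in the division zone, 712 and 1 at 6 h there, and 1582 and 0 at 6 h in the elongation zone. At 14 h against the end of the night they were 7640 and 0, 8129 and 0, and 10071 and 1826 from base to tip. At 24 h they were 5762 and 0, 7442 and 1, and 10161 and 1034, and 7822 and 0 for 14 h against the end of the day in the division zone.

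For the interactions at 24 h the splits cannot decide whether the zones differ beyond chance. Splits that keep the times of 1 zone whole still carry that zone's own change, so they reach high counts whether or not the zones differ. Against the division zone the real split was 1 of 100 (8687; highest other 8324), and the highest among splits that mixed the times of both zones was 63. Against the elongation zone 2 of 100 reached the real count (8546), the other being the swap of both times in 1 zone (10096), which keeps the groups whole; the highest without that swap was 8239, and among splits that mixed both zones 29.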

How the results depend on the processing

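No named gene or called list turned direction under any alternative. Of 940 named results, 918 kept their call after centring, 911 after quantile normalization, 932 with trend and robust settings, 890 with array weights, 832 with the compared groups alone and 506 with a minimum of 1, and all 850 that could be tested kept it without dim probe sets. Leaving out 1 array kept 6170 calls and ended 408.

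Counts of called probe sets stayed within 1.5 times except as follows. With the compared groups alone: night, division zone 2825 and mature zone 2520; 6 h, 1859 and 2180; 14 h, mature zone 5589; interaction at 6 h with the elongation zone 2357. Array weights gave 4792 and 2563 for the night in the growth zones and 5257 and 3337 at 6 h. In the division zone at 24 h they gave 9009. Most growth-zone arrays had higher weights than the mature-zone arrays, and beyond that the cause was not tested. A minimum of 1 left, by construction, from base to tip: night 78, 125 and 1486; 6 h 154, 216 and 1368; 14 h 1463, 1794 and 2719; 24 h 560, 1167 and 3460; 14 h against the end of the day 1535, 2015 and 3727. It left 1406 and 6062 for the steps along the leaf, 1116 and 988 for the interactions at 6 h, 3255 and 3260 at 24 h and 1405 for the night. Leaving out 1 array gave 582 to 803 and 333 to 907 for the night in the growth zones, 388 to 607 and 716 to 1525 at 6 h, and 2919 to 5012 and 2625 to 4373 for the interactions at 6 h. Where it left 1 array in a group, that array was assumed to vary like the others.

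Of 35 called lists 2 kept their call with an estimated correlation, 34 against all probe sets, 32 with the mean of probe sets and 31 with every symbol match. All 35 also passed fry, which tests a list against no change and not against other genes, so it does not support the call of camera. Without dim probe sets 21 kept it and 13 lost it, and these are named with their values beside each list. Same-numbered arrays of different zones at the same time tended to deviate together. Of 40 such pairs 45% correlated above 0.1 (median 0.1), against 9.0% of differently numbered pairs at the same time. Deviations cancel out within a group, so a correlation of same-numbered pairs lowers that of the others. Between arrays of another zone and another time the shares were 21.8% for the same number and 21.1% for another number. Between the division and elongation zones they did at the end of the night (0.21 to 0.33), 14 h (0.14 to 0.46) and 24 h (0.22 to 0.42), though not in each pair at 6 h (lowest 0.03) or at the end of the day (−0.03 and 0.06), the only time at which these zones were compared by test. The replicate number as a block gave 1123 for the night in the division zone and 10134 at 24 h in the mature zone. It ended 6 calls of genes, while time and number together as a random block ended none. The alternative without the 3 arrays whose labels lack the genotype was not run, since these are the 3 empty columns. Signal near background limits probe sets at levels such as the 4.12 of the reporter probe sets.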

Other observations

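Water channel genes were among those that changed over the night and in the extended night. The 22 aquaporins on the array and the genes of benzoxazinoid synthesis were chosen after the data were seen, so counts and values are given and no test of either group. In the night *pip1e* rose by 3.70 ± 0.16 in the mature zone, *pip2b* by 2.93 ± 0.15 and *pip2c* by 1.81 ± 0.12, while *tip4a* fell by 3.41 ± 0.13 (limma, n = 2 and 3). Of the 22, 10 rose and 1 fell there, 5 and 1 in the elongation zone and 3 and 0 in the division zone. From the division to the elongation zone 12 were higher and 1 lower. After 24 h of extended night *tip2a* was higher by 1.32 ± 0.35 in the division zone and 2.16 ± 0.35 in the elongation zone and fell by 3.44 ± 0.35 in the mature zone, where 6 of the 22 rose and 10 fell.

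At 24 h *bx1*, of the synthesis of benzoxazinoids, the defence compounds of young maize, fell, at −3.14 ± 0.27 in the division zone, −1.33 ± 0.27 in the elongation zone and −1.30 ± 0.27 in the mature zone. The transcript of *bx6* fell, at −0.99 ± 0.23 in the division zone and −3.16 ± 0.23 in the mature zone, and was not called in the elongation zone (−0.53 ± 0.23, adjusted p = 0.062, limma, n = 3 and 3). At 6 h neither gene was called in the growth zones, while both fell in the mature zone, *bx1* at −0.98 ± 0.31 and *bx6* at −1.94 ± 0.26. Already over the normal night *bx6* fell by 2.20 ± 0.26 in the mature zone, and 1 of the 2 genes was called lower in the elongation zone.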
